A study of Homo sapiens with 18 samples.

How the data were processed

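The series holds total RNA of MDA-MB-231 cells, a human triple-negative breast cancer line, labelled with biotin and hybridised to Affymetrix human transcriptome arrays. Per the labels, 3 samples were untreated controls, 3 had received 10 nM paclitaxel (PTX) and 3 carried exogenous TRA2A (231T). Each sample appears at gene level and at exon level, so 9 titled samples give 18 entries. The groups and the replicate numbers were taken from the sample titles. The descriptions of control 2 and control 3 name the cells MDA-MB-232 and MDA-MB-233, while their source and cell line fields read MDA-MB-231, which was used. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

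The deposited values are log2 intensities, a unit read from their range. The arrays were processed with Affymetrix Expression Console 1.3.1 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalises arrays that are processed together and summarises probes, and it compresses differences of dim probe sets. The version of RMA, the genome build and the probe annotation release are not given in the sources used here. No further scaling was applied for the main results. Scanner files were not analysed here, so background correction could not be varied and no detection calls were made. Depth has no direct counterpart on arrays: the number of arrays, 3 per group, limits the precision, and signals near the background sets carry little information.

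The gene-level table holds 70523 entries, of which 2995 control sets were left out of the tests, leaving 67528 transcript clusters. By the platform annotation, 23781 clusters have 1 gene symbol, 1543 have several and 42204 have none. Only clusters with 1 symbol were named, and a gene was represented by its cluster with the highest mean over the 9 arrays, which gave 22411 symbols. Older symbols were updated through a RefSeq table of assembly GRCh38.p14, used for names and for which genes contain each other, and no coordinate was taken from it. The tables hold 1718 gene-level entries that repeat the values of another entry.

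The exon-level table holds 573909 exon-region and 339146 junction probe sets. Of the exon-region sets, 385548 have 1 symbol, 23151 several and 165210 none. The same 2995 control sets occur in both tables, which allowed the tables to be compared array by array. The 231T columns were equal in 100% of these sets within 0.001. In control and PTX columns the median absolute difference between tables lay between 0.245 and 0.253 on the log2 scale. The control and PTX columns of the exon-level table thus came from another RMA run than its 231T columns. The spread of that offset was measured on the 1465 shared sets that are exon regions or junctions, and it is given with the 231T results at exon level.

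Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on a group-means model over all 9 arrays with 6 residual degrees of freedom and no replicate block. Tests were two-sided and a cluster was called at a Benjamini-Hochberg adjusted p under 0.05. Values are given as mean ± SD of 3 arrays, and differences as log2 fold change with its standard error (SE). Values were read with the R package data.table (version 1.17.8) and with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Exon use was tested with limma's diffSplice and the Simes test per gene, over exon-region sets with 1 symbol, a mean of at least 5.22 (the median of such sets) and at least 3 sets per gene. That left 186741 sets in 13207 genes. Gene lists were tested with limma's camera at its preset correlation of 0.01, over 1 cluster per symbol, with Benjamini-Hochberg adjustment over 29 lists. An estimated correlation and limma's fry were run as alternatives. The directional p of fry tests whether the members of a list move one way on balance, and it does not compare the list with other genes.

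The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists cover mitosis, DNA replication, histones, tubulins, microtubule-associated proteins, taxane transport and metabolism, p53 targets, apoptosis regulators, inflammatory cytokines, interferon-stimulated genes, mesenchymal, epithelial and stemness genes, SR and hnRNP splicing factors, the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock proteins, cholesterol and fatty acid synthesis, hypoxia and glycolysis, AP-1 and immediate early genes, YAP/TEAD targets, matrix and invasion genes, autophagy and lysosome, luminal, basal, fibroblast and leukocyte markers, and genes with TRA2-regulated exons. Named genes per comparison were TRA2A, TRA2B, RSRC2, CALU, PALM and HNRNPM, which are known from the study. To these were added the 6 largest rises and 6 largest falls among called genes whose groups did not overlap. From the 6 lists with the highest share of called members, the 3 called members with the largest change were taken, and from every other list the called member with the smallest adjusted p. For exon use they were the same study genes and, against control, the 8 genes with the smallest adjusted p. Genes named outside this rule are said to have been chosen after their values were seen.

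The alternatives were other scalings (quantile, cyclic loess, centring on the median), a filter on dim clusters, only clusters with 1 symbol, eBayes with trend and robust settings, only the 2 groups compared, array weights, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. For exon use they were other filters, junction sets, the F test and a 2-group fit. Counting identical entries once, testing each probe set against its own spread, and bounds from the offset between runs, over all levels and by 10 groups of level, were added after seeing the data.

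Each procedure was tested on simulated data with known changes in 200 genes. At gene level limma recovered 75%, 73% and 67% of changes of log2 1 for PTX against control, 231T against control and 231T against PTX, and 98%, 99% and 99% of changes of log2 2, with 7, 8 and 11 false calls among 67528 clusters. For exon use over 13207 genes, diffSplice recovered 87%, 87% and 80% of log2 2 changes and 18%, 9% and 7% of log2 1 changes, but 66.8%, 66.4% and 66.9% of its calls were false. diffSplice pools the spread over the probe sets of a gene, which are not equally variable here. A second test was therefore added after seeing the data, which used the spread of each probe set relative to the rest of its gene. In the same simulations 11.5%, 5.26% and 10% of its calls were false, while it recovered 53%, 36% and 44% of log2 2 changes and 1%, 0% and 1% of log2 1 changes. Main counts of both tests are given together, and the alternatives and left-out arrays were run with diffSplice. The camera procedure, tested for PTX against control over 22411 genes, found a list shifted by 0.5 and called 0 other lists. That test covered 1 planted shift in 1 comparison, so it does not show whether the preset correlation suits the real lists.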

Results

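RNA levels were measured on human transcriptome arrays in MDA-MB-231, a triple-negative breast cancer cell line, in 3 groups of 3 samples. The groups were untreated cells (control), cells given 10 nM paclitaxel (PTX), a drug that binds β-tubulin and stabilises microtubules, and cells with exogenous TRA2A (231T), an RNA-binding protein that regulates alternative splicing. Each sample was summarised per gene and per exon region. Median gene-level log2 intensities lay between 4.03 and 4.25, and those of the antigenomic background sets between 3.71 and 3.84, so a typical transcript cluster was close to background. Across clusters, Pearson correlations between arrays were 0.9881 to 0.9905 within control, 0.9791 to 0.9862 within PTX and 0.9843 to 0.9893 within 231T. They were 0.9715 to 0.9852 between control and PTX and 0.9516 to 0.9614 between control and 231T. The array of PTX 1 stood nearer to the 231T arrays (0.9682 to 0.9705) than those of PTX 2 and PTX 3 did (0.9355 to 0.9511). The first principal component held 56.1% of the variance and the second 14.3%.

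TRA2A, cluster TC07001197.hg.1, had a log2 level of 6.87 ± 0.33 (SD, n = 3) in control, 7.91 ± 0.37 in PTX and 9.33 ± 0.12 in 231T. It rose by 2.46 in 231T over control (SE 0.21, limma adjusted p = 0.00025), a check of the 231T label, and was higher in 231T than in PTX by 1.42 (SE 0.21, limma adjusted p = 0.00326). In PTX it lay 1.04 above control (SE 0.21), with all 3 PTX arrays above all 3 control arrays, but with a limma adjusted p of 0.0618. Over 19 alternatives that adjusted p ranged from 0.0325 to 0.177 and the difference from 0.84 to 1.2, and 4 of the alternatives called it. Among 27 exon-region probe sets of TRA2A, 24 were higher in PTX than in control and 5 rose, with a median of 1.5. In 231T, 17 rose and 2 fell, with a median of 2.66. Of 16 TRA2A junction sets 9 rose in 231T (median 2.82), and in PTX limma called 0, with 10 at an unadjusted p under 0.05 and a median of 1.43. The exon-level 231T columns came from another RMA run than the control and PTX columns, with an offset between runs of SD 0.332 and a 99th percentile of 0.999 in distance from its mean for 231T against control.

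**Figure D1:**
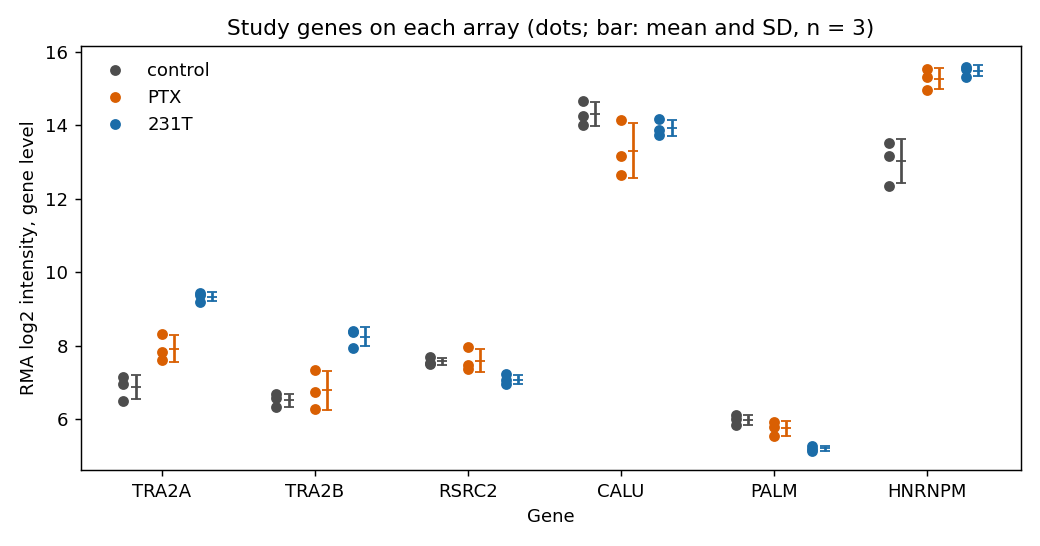
Gene-level RMA log2 intensity (vertical axis) of TRA2A, TRA2B, RSRC2, CALU, PALM and HNRNPM on each of the 9 arrays as dots, with the mean and SD of 3 arrays per group as bars. TRA2A means were 6.87 in control, 7.91 in PTX and 9.33 in 231T, and HNRNPM means were 13.01, 15.27 and 15.48.

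**Figure D2:**
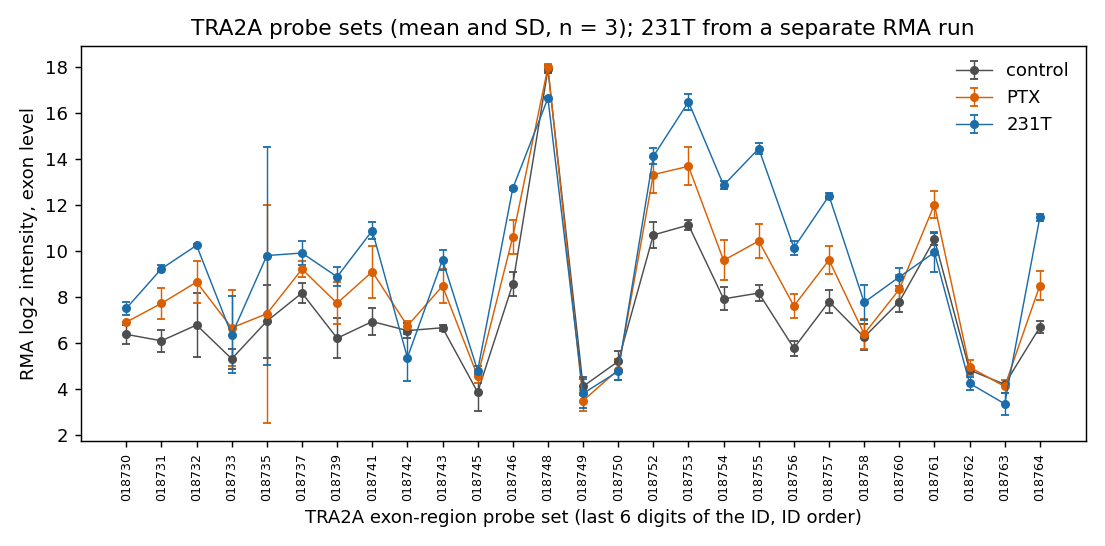
Exon-level RMA log2 intensity (vertical axis) of the 27 exon-region probe sets of TRA2A in the order of their identifiers, with the mean and SD of 3 arrays per group and 231T from a separate RMA run (SD of the offset 0.332). The median difference from control was 1.5 in PTX and 2.66 in 231T.

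PTX was compared with control to show how the cells' RNA differed under paclitaxel. HNRNPM, a splicing regulator of the hnRNP family, rose by 2.26 on the log2 scale, from 13.01 ± 0.60 to 15.27 ± 0.29 (SD, n = 3). The other largest rises were the small nucleolar RNAs SNORA20 (2.49), SNORD63 (2.24), SNORD117 (2.06) and SNORD9 (2.06), which guide chemical modification of other RNAs, and H1-6 (2.25), a linker histone known from testis. MIR3143, a microRNA gene, fell by 5.74, from 12.91 ± 1.04 to 7.17 ± 0.45. DUSP1, a phosphatase that switches off MAP kinases, fell by 2.66, from 10.24 ± 0.24 to 7.58 ± 0.20. UGCG, which glucosylates ceramide, fell by 2.51 and CCN2, a matricellular protein, fell by 2.26. DUSP5, a phosphatase of ERK, fell by 2.18, and the adhesion receptor ADGRF1 fell by 2.15. The limma adjusted p-values of these 12 genes lay between 0.000344 (DUSP1) and 0.0498 (SNORA20). RSRC2 (0.03), TRA2B (0.27), PALM (-0.23) and CALU (-1.0) were not called, with adjusted p between 0.267 and 0.982.

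In all, limma called 654 of 67528 clusters for PTX against control, 154 higher and 500 lower, and 7842 had an unadjusted p under 0.05. Of the 22411 gene symbols 341 were called (1.52%), 59 higher and 282 lower. Of the called clusters 302 changed at least 2-fold. The share of calls that were higher was 23.6% as deposited, 38.4% after cyclic loess scaling, 46.3% without PTX 1 (475 higher, 550 lower) and 9% without control 3 (9 higher, 91 lower), so the balance of directions depended on single arrays. The count without 1 array was 140 (control 1), 218 (control 2), 100 (control 3), 1025 (PTX 1), 149 (PTX 2), 287 (231T 1) and 327 (231T 2). Of the 32 named genes called in this comparison, MIR3143, DUSP1, CCN2 and ITGB4 kept their calls in all 19 alternatives. Leaving out control 1, 2 or 3 ended 23, 18 or 27 of the 32 calls, PTX 1, 2 or 3 ended 9, 20 or 11, and 231T 1, 2 or 3, which only add to the estimate of the spread, ended 16, 13 or 5, and no direction changed. ADGRF1 and those 4 genes were the ones that stayed called without control 3.

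Genes of DNA replication and the G1/S transition were higher in PTX than in control in 26 of 26 measured members, with a median of 0.84. Over all genes tested 3 of them rose: CDC6, which loads the replicative helicase (1.68), UHRF1, which maintains DNA methylation (1.19), and TYMS, thymidylate synthase (1.03). Adjusted over the list alone, 20 rose and 0 fell. The camera adjusted p was 4.15e-18, and the adjusted p = 0.312 with an estimated correlation. Of 13 replication-dependent histones, H2BC5 (0.96) and H2AC6 (0.82) rose, 7 rose adjusted over the list alone, and the camera adjusted p was 2.46e-05 (adjusted p = 0.312 with an estimated correlation). Of 29 genes of G2/M and mitosis, 24 were higher, with a median of 0.45 and a camera adjusted p of 1.15e-05, but limma called 0 of them (8 higher and 1 lower at an unadjusted p under 0.05), and 5 rose and 1 fell adjusted over the list alone. With an estimated correlation that list had an adjusted p = 0.492. HNRNPM was the 1 called member of 18 hnRNP proteins (camera adjusted p 0.000233, adjusted p = 0.458 with an estimated correlation, 7 rose and 1 fell adjusted over the list alone). IFI27, an interferon-induced mitochondrial protein, rose by 1.81 as the 1 called member of 28 interferon-stimulated genes (camera adjusted p 0.000116, adjusted p = 0.458 with an estimated correlation, 3 rose adjusted over the list alone). Each of these single-gene calls was lost without control 3, and their highest adjusted p over 19 alternatives lay between 0.0545 (IFI27) and 0.133 (CDC6).

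YAP/TEAD target genes were lower in PTX, with a median of -0.47 over 18 members. CCN2 fell by 2.26, CRIM1, a membrane protein that binds bone morphogenetic proteins, by 1.84 and the LIM domain protein AJUBA by 1.26. CCN1, named after its values were seen, was the last of 4 members that fell, and 13 fell adjusted over the list alone. The camera adjusted p was 2.87e-08 (adjusted p = 0.312 with an estimated correlation). Of 23 AP-1 and immediate early genes, 4 fell, with a median of -0.32: DUSP1, DUSP5, the transcription factor MYC (-1.47) and DUSP6, which was named after its values were seen. Adjusted over the list alone 9 fell, and the camera adjusted p was 1.91e-07 (adjusted p = 0.312 with an estimated correlation). Of 21 genes of the integrated stress response 1 was higher, and ATF4, the transcription factor at its centre, fell by 1.05, with 6 falls adjusted over the list alone. Its camera adjusted p was 1.43e-05, with an adjusted p = 0.479 with an estimated correlation. WIPI1 (-1.49) and GABARAPL2 (-0.82), which act in autophagosome formation, fell among 19 autophagy and lysosome genes (camera adjusted p 0.00747, adjusted p = 0.492 with an estimated correlation, 4 fell and 1 rose adjusted over the list alone). SREBF2, a transcription factor of sterol synthesis, fell by 0.75 among 23 genes of cholesterol and fatty acid synthesis (camera adjusted p 0.0298, adjusted p = 0.492 with an estimated correlation, 5 fell adjusted over the list alone). The cholesterol list was not called without control 1 or PTX 2, after quantile scaling, or among clusters at or above the median level. The autophagy list was not called without PTX 2 or among clusters at or above the median level. Apart from CCN2 and DUSP1, each gene whose change is given here lost its call without control 3, with a highest adjusted p over 19 alternatives between 0.0778 (DUSP5) and 0.155 (SREBF2).

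Camera called 10 of the 29 lists for PTX against control, 0 lists passed with an estimated correlation, and fry called 3 (replication, AP-1 and YAP/TEAD). Other lists held called members without a camera call. FN1, fibronectin (1.97), CDH11, a mesenchymal cadherin (1.96), and the repressor SNAI2 (0.62) rose among 22 mesenchymal genes, whose median was -0.06. TUBB4B, a β-tubulin, rose by 1.03 among 15 tubulins and the Notch ligand JAG1 by 1.42 among 17 stemness genes. ITGB4, the integrin β4 subunit, fell by 1.42 and PLAU, the urokinase gene named after its values were seen, also fell among 23 matrix and invasion genes. GDF15, a stress-induced cytokine, fell by 1.26 among 21 p53 targets. Without control 3 the calls of FN1, CDH11, SNAI2, TUBB4B, JAG1 and GDF15 were lost. The highest limma adjusted p of these genes over 19 alternatives lay between 0.0576 (FN1) and 0.158 (SNAI2). The lists without a camera call had camera adjusted p between 0.0648 (tubulins) and 0.954. Counts adjusted over the list alone were 3 rises for tubulins, 3 rises and 6 falls for mesenchymal genes, 3 and 3 for matrix genes, 3 falls for p53 targets, 1 rise and 5 falls for epithelial genes and 3 rises and 2 falls for luminal markers. In 15 lists limma called 0 members, and 61 of their 276 members had an unadjusted p under 0.05. Besides mitosis these were microtubule-associated proteins, taxane transport, apoptosis regulators, cytokines, epithelial genes, SR splicing factors, ER chaperones, heat shock proteins, hypoxia, luminal, basal, fibroblast and leukocyte markers, and genes with TRA2-regulated exons. For microtubule-associated proteins (median 0.04, mean -0.01), matrix genes (0.02 and -0.01) and leukocyte markers (0.06 and -0.04), which camera placed up, and epithelial genes (0.02 and -0.07) and basal markers (0.01 and -0.11), which it placed down, the median and the mean differed in sign. ER chaperones had a median of -0.06 and a mean of -0.07 while camera placed them up.

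Exon use, the change of a probe set relative to the rest of its gene, was compared because TRA2A and hnRNP proteins are splicing regulators. For PTX against control, diffSplice called 798 of 13207 genes (2438 at an unadjusted p under 0.05), and the test on each probe set's own spread called 13 (2076 unadjusted). All 13 were among the diffSplice calls. In simulations with 200 changed genes 66.8% of the diffSplice calls and 11.5% of the own-spread calls for this comparison were false, shares that do not carry over to another number of changed genes. HNRNPM was called by both tests (adjusted p 2.49e-06 and 0.0114). Of its 19 sets diffSplice called 1, PSR19002356.hg.1, which changed by -0.42, from 6.92 ± 0.69 to 6.50 ± 0.26 (SD, n = 3). The median of its gene stood at 2.31, a relative change of -2.69 (SE 0.39). That set is dim, and a dim set that responds less can look like a change in exon use. HNRNPM kept its call in all 18 alternatives (highest adjusted p 0.0442), among them the filter at the 75th percentile of level (7.58), which leaves this set out. CALU, a calcium-binding ER protein, had a relative change of 2.3 in PSR07012309.hg.1, from 6.10 ± 0.43 to 7.35 ± 0.78 (SD, n = 3), with adjusted p 0.00923 in diffSplice and 0.0634 by own spread. Its call was also lost with an F test per gene (0.115) and among sets at or above the 75th percentile of level (0.691). PALM, a membrane-associated protein, had adjusted p of 0.0123 and 0.119. Without control 1 or control 3 diffSplice gave 0.12 and 0.22 for CALU and 0.123 and 0.117 for PALM, and for PALM 0.0598 without PTX 1 and 0.106 without PTX 2. RSRC2 (0.106), TRA2B (0.289) and TRA2A (0.937) were not called. Over 18 alternatives their adjusted p ranged from 0.00232 to 0.39, 0.0111 to 0.997 and 0.00628 to 1. RSRC2 was called without PTX 1 (0.00232), without PTX 3 (0.0127) and at the 75th percentile (0.0155), TRA2A without PTX 1 (0.00628) and TRA2B with the F test (0.0111). The RSRC2 set with the smallest p, PSR12027344.hg.1, stood at 9.6, 3.81 and 9.01 in PTX 1, 2 and 3. In control 1, 2 and 3 it stood at 10.02, 9.27 and 9.03, so its PTX difference (-1.97) rests on PTX 2. Of the 8 genes with the smallest diffSplice p, the cadherin CDH11 (0.00774), the cytokine receptor OSMR (0.0194) and FBRSL1 (0.0287) were also called by own spread, while HLA-B (0.171), SLC25A6 (0.0963), FCHSD1 (0.0669), EXOC7 (0.0554) and KIFC1 (0.073) were not. The diffSplice count was 495 without control 1, 328 without control 3 and 402 without PTX 2.

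231T was compared with control to show how the RNA of cells with exogenous TRA2A differed from that of untreated cells. The labels name no group given an empty vector, so effects of TRA2A and of introducing it cannot be told apart. TFRC, the transferrin receptor, rose by 4.98, from 7.47 ± 0.19 to 12.45 ± 0.35 (SD, n = 3). CDC6 rose by 4.01, TFPI2, a protease inhibitor, by 3.46, THBS1, thrombospondin 1, by 3.33, SLC7A11, the cystine transporter, by 3.28 and NEMP1, a nuclear envelope protein, by 3.26. TNS4, a focal adhesion protein, fell by 6.06, from 11.04 ± 0.25 to 4.98 ± 0.10. MIR3143 fell by 5.74, IGFBP4, which binds insulin-like growth factors, by 4.77, and the small RNA genes RNU5D-2P, SNORD58C and SNORD99 by 6.17, 5.19 and 4.69. The limma adjusted p-values of these 12 genes lay between 7.03e-05 and 0.00619.

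Of the study genes, HNRNPM rose by 2.47 in 231T (limma adjusted p = 0.000653) and TRA2B, the paralog of TRA2A, by 1.72 (0.00216), while PALM fell by 0.78 (0.00323). RSRC2 (-0.49, adjusted p 0.0716) and CALU (-0.37, 0.529) were not called. In all, limma called 10814 of 67528 clusters, 4837 higher and 5977 lower, and 4248 at least 2-fold. Of the 22411 gene symbols, from which the lists are drawn, 5330 were called (23.8%), 2858 higher and 2472 lower. Over clusters the higher calls were 44.7% as deposited and 52.5%, 53.3% and 52.5% after quantile scaling, centring and cyclic loess. Which direction held more calls thus depended on the scaling and on counting clusters or symbols. Without control 3 the count was 7122. Of 52 named genes called, 50 kept their calls in all 19 alternatives.

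Genes of DNA replication and G1/S rose in 231T in 24 of 26 cases, with 0 falls and a median of 1.56. Besides CDC6, the primase PRIM1 rose by 2.84 and the flap endonuclease FEN1 by 2.76. In all 24 rose adjusted over the list alone, and the camera adjusted p was 9.61e-16 (adjusted p = 0.613 with an estimated correlation). Of 29 mitotic genes 8 rose, among them the chromokinesin KIF4A (1.39), and 4 fell (camera adjusted p 0.0763). Those 4, named after their values were seen, were PLK1, KIF20A, PTTG1 and UBE2C. With 1 array left out, the called mitotic genes numbered 4 to 16 rises and 2 to 5 falls. Of 31 SR and SR-related splicing factors 16 rose and 4 fell, with a median of 0.65: SRSF1 rose by 3.03, SRSF7 by 2.06 and SRSF3 by 2.06. The 4 that fell, named after their values were seen, were SRRM1, SRRM2, CLK2 and CLK3. Adjusted over the list alone 20 rose and 6 fell (camera adjusted p 8.11e-05, adjusted p = 0.613 with an estimated correlation). Of 18 hnRNP proteins 11 rose, with HNRNPR (2.01) and HNRNPA2B1 (1.90) next to HNRNPM, and PCBP2, named after its values were seen, fell. Their median was 1.1, 11 rose and 2 fell adjusted over the list alone, and the camera adjusted p was 0.00235 (adjusted p = 0.613 with an estimated correlation).

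Interferon-stimulated genes, epithelial genes and immediate early genes were lower in 231T. Of 28 interferon-stimulated genes 8 fell and 0 rose, with a median of -0.21, and IFITM1, which restricts virus entry, fell by 1.95, from 7.97 ± 0.03 to 6.02 ± 0.04 (SD, n = 3). There were 10 falls adjusted over the list alone, and the camera adjusted p was 0.00363 (adjusted p = 0.613 with an estimated correlation). Of 24 epithelial genes 7 fell and 0 rose, with a median of -0.13, and the keratin KRT19 fell by 1.94. The falls numbered 7 adjusted over the list alone, and the camera adjusted p was 0.036 (adjusted p = 0.613 with an estimated correlation). That list lost its call after quantile scaling and without 231T 3. Of 23 AP-1 and immediate early genes 11 fell and 2 rose, with a median of -0.75, and DUSP1 fell by 2.39. There were 14 falls and 2 rises adjusted over the list alone, and the camera adjusted p was 0.012 (adjusted p = 0.613 with an estimated correlation). The risers, named after their values were seen, were JUN and IER2. Camera called these 6 lists, 0 passed with an estimated correlation, and fry called 12.

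Other lists had called members in both directions in 231T and no camera call. Among 17 apoptosis regulators 6 rose and 4 fell: BIRC2, an inhibitor of apoptosis, rose by 2.38, and the anti-apoptotic BCL2 family members BCL2A1 and MCL1 rose by 1.83 and 1.82. Without control 2 or 231T 1 BCL2A1 lost its call, with a highest adjusted p of 0.0631 over 19 alternatives. Among 15 heat shock proteins 7 rose and 3 fell, with DNAJA1, a co-chaperone, up by 2.79, HSP90AA1 up by 1.72 and HSPB1 at -2.33. Of 23 matrix and invasion genes 7 rose and 6 fell, and ITGB4 fell by 4.46, from 9.97 ± 0.21 to 5.51 ± 0.06 (SD, n = 3). Of 21 stress response genes 8 rose and 3 fell, and DDIT4, an inhibitor of mTORC1, fell by 1.97. Among 19 autophagy and lysosome genes 4 rose and 7 fell, with the protease CTSD at -2.54. PTGS2, cyclooxygenase 2, rose by 2.3 among 24 cytokine and NF-kB genes, of which 7 rose and 1 fell. GDF15 fell by 2.18 among 21 p53 targets, of which 8 rose and 2 fell. TGFB2, held by both lists, fell by 2.28 among 22 mesenchymal genes (3 rose, 4 fell) and 18 YAP/TEAD targets (4 rose, 5 fell). ACAT2, an enzyme of cholesterol metabolism, rose by 2.08 among 23 lipid synthesis genes (6 rose, 5 fell), PDK1 by 1.08 among 22 hypoxia genes (6 rose, 3 fell), and JAG1 by 1.99 among 17 stemness genes (3 rose, 1 fell).

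Of the lists closest to the treatment in this series, 25 microtubule-associated proteins had 2 rises and 5 falls in 231T, with MAP4 at -1.41, and 15 tubulins had 3 rises and 2 falls, with TUBB4B up by 0.91. Among 16 genes of taxane transport and metabolism 4 rose and 2 fell, with the exporter ABCC3 at -1.18. Of 9 genes with TRA2-regulated exons 4 rose and 2 fell: NASP, a histone chaperone, rose by 1.76, TRA2B by 1.72, and MAPT, the gene of tau, fell by 1.48. Of 13 histones 2 rose, H2AC6 (0.46) and H2BC12, the latter named after its values were seen. H2AC6 lost its call without any 1 of control 1, control 2, control 3, PTX 3, 231T 1, 231T 2 and 231T 3 (highest adjusted p over 19 alternatives 0.134). Of 19 ER chaperones 4 rose and 2 fell, with DNAJB11 up by 1.55, although a second cluster of that gene stood at -0.61. Some luminal, basal and fibroblast markers were called as lower: 5 of 14 luminal markers fell, with SPDEF at -1.0, 2 of 9 basal markers with ACTA2 at -0.57, and 2 of 10 fibroblast markers with PDGFRB at -0.63. The shares called were 35.7%, 22.2% and 20%, against 23.8% of all gene symbols, so the basal and fibroblast shares were not above it. The median control level was 3.93 for the fibroblast and 3.94 for the leukocyte list, near the background sets, and 4.68 for the basal list. CD68 fell by 1.81 as the 1 called leukocyte marker of 12, and had a level of 15.21 ± 0.39 (SD, n = 3) in control. The camera adjusted p of the lists that were not called lay between 0.0592 (luminal markers) and 0.928. Adjusted over the list alone, the counts of rises and falls became 10 and 5 for mitosis, 4 and 6 for microtubule-associated proteins, 7 and 4 for apoptosis, 7 and 4 for heat shock, 8 and 6 for lipid synthesis, 6 and 5 for hypoxia, 6 and 7 for autophagy, 7 and 7 for matrix genes, 5 and 3 for genes with TRA2-regulated exons, 4 and 1 for stemness genes, 2 and 1 for histones, 1 and 5 for luminal markers and 0 and 3 for basal markers, and did not change for the other lists without a camera call.

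Other members of the short counts, named after their values were seen, completed these groups in 231T. CLASP2 and MAPRE1 rose and MAPRE3, MAPT, STMN3 and TBCD fell beside MAP4. TUBB6 and TUBE1 rose and TUBB4A and TUBG2 fell, and ABCC4, ABCC5, CYP1B1 and SLCO1B3 rose while ABCC1 fell. CHEK1 and HIPK3 rose and PALM fell among genes with TRA2-regulated exons. BAD, BCL2L1, BMF and CASP9 fell among apoptosis regulators, CRYAB and HSF1 among heat shock genes, CHAC1 and NUPR1 among stress response genes, ICAM1 among cytokine genes and CCNG1 among p53 targets. LOX, SNAI2 and TGFBI rose and AXL, S100A4 and TGFB1 fell among mesenchymal genes. AMOTL1, PTPN14, TEAD1 and WWC1 rose and ARHGEF17, CCN2, CRIM1 and NUAK2 fell among YAP/TEAD targets. FASN, LSS, MVD, SREBF1 and SREBF2 fell among lipid synthesis genes, PFKFB4, SLC2A1 and SLC2A3 among hypoxia genes, and HERPUD1 and PDIA4 among ER chaperones, of which CANX, DNAJC3 and EDEM1 rose. ATG5, ATG12, BECN1 and MCOLN1 rose among autophagy genes, and CD44 and SOX9 rose and CD24 fell among stemness genes. AGR2, ERBB3, KRT8 and MLPH fell beside SPDEF, MYLK beside ACTA2 and FBLN1 beside PDGFRB.

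The median and the mean differed in sign in 231T for histones (-0.03 and 0.03), taxane transport (-0.02 and 0.15), ER chaperones (-0.07 and 0.07), lipid synthesis (-0.05 and 0.16), hypoxia genes (-0.001 and 0.14) and matrix genes (-0.09 and 0.06), which camera placed up, and for microtubule-associated proteins (0.03 and -0.04), which it placed down.

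**Figure D3:**
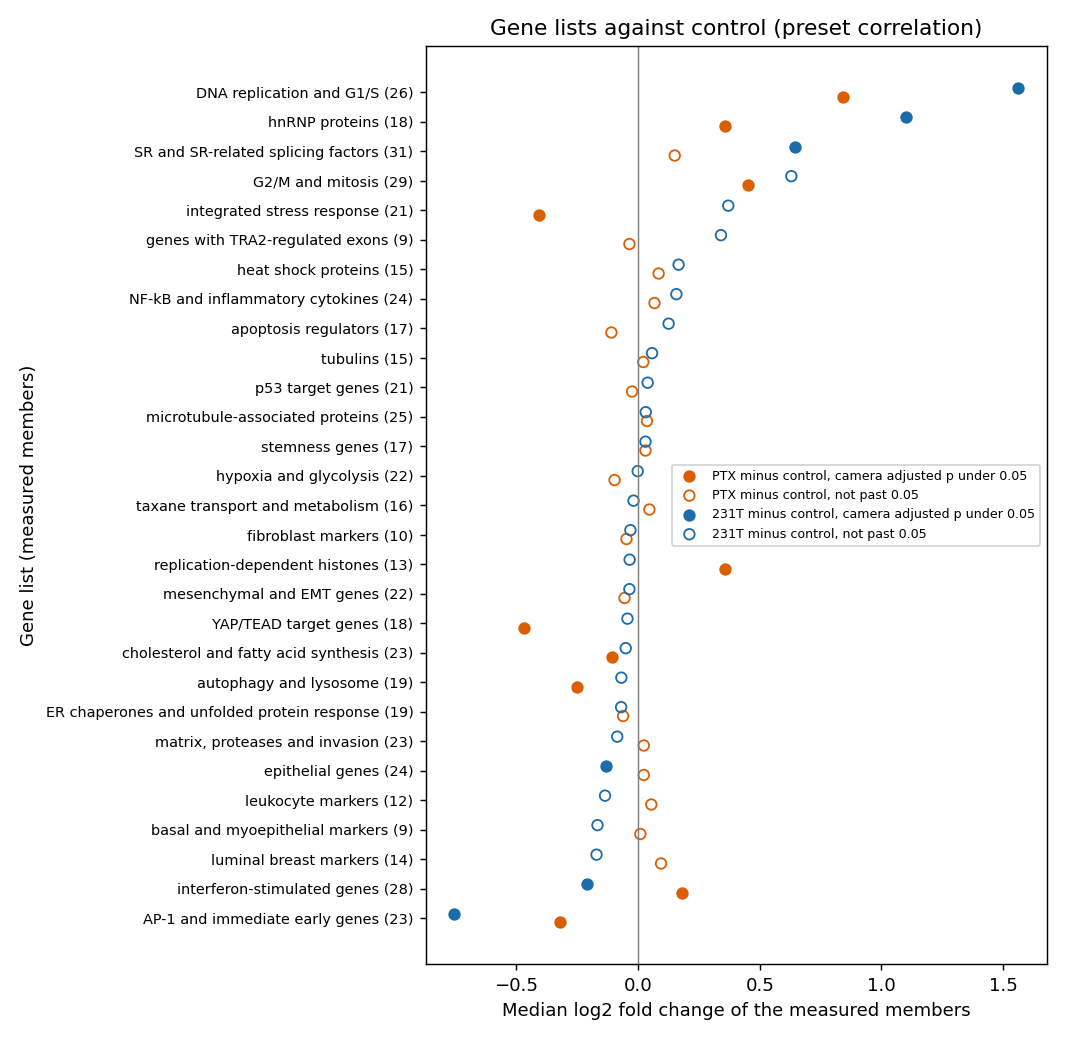
Median log2 fold change (horizontal axis) of the measured members of the 29 gene lists for PTX minus control and 231T minus control, with the number of members beside each name and filled dots where the camera adjusted p at the preset correlation was under 0.05. The replication list stood highest in both, at 0.84 and 1.56, and 0 lists passed with an estimated correlation.

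At exon level, diffSplice called 10378 of 13207 genes for 231T against control, and the own-spread test called 10874, with 10026 genes called by both. In simulations with 200 changed genes 66.4% and 5.26% of their calls were false (190 and 2 genes), shares that do not carry over to counts of this size. The 231T columns came from another RMA run than the control columns, and between the tables this comparison was offset by -0.13 on average (SD 0.332) with a 99th percentile of 0.999 in distance from that mean. The offset depended on level, with means from -0.36 to 0.28 in 10 groups of the shared sets by level, and the median of all sets was 4.70 to 4.75 in 231T columns and 5.10 to 5.18 in the others. Of the diffSplice genes, 9943 held a called relative change above 0.999, and 6115 one above 1.7, the highest 99th percentile of the offset in any of these groups, in distance from the mean of any of them. All 6 study genes were called by both tests: TRA2A (diffSplice adjusted p 0.000109), TRA2B (1.21e-11), RSRC2 (3.61e-07), CALU (1.41e-07), PALM (0.000137) and HNRNPM (8.96e-14). Of all tested genes diffSplice called 78.6% and own spread 82.3%, so such calls are not particular to these 6 genes. TRA2A sets ranged from 6.27 (PSR07018755.hg.1) to -1.26 (PSR07018748.hg.1). Exogenous TRA2A may lack parts of the gene, and sets it does not cover would not rise with it. The TRA2A call can thus come from the exogenous copy alone. The call of CALU was lost among sets at or above the 75th percentile of level (0.267). In CALU the probe set PSR07012309.hg.1 rose relative to its gene by 3.33 (SE 0.51), and in RSRC2 the relative change of PSR12027344.hg.1 was -3.73 (SE 0.58). That RSRC2 set was also low on the array of PTX 2 (3.81). The 8 genes with the smallest p had relative changes of 8.51 in ABCC3, 8.08 in GLG1, 7.25 in PDK2, 6.9 in CSAD and 4.32 in HSPG2, and of -8.12 in PABPC1, -8.01 in MUC5B and -4.59 in PBX2. The MUC5B set went from 18.58 to 5.35, with a gene median of -4.41. In 231T the PBX2 set stood at 2.58, below the 25th percentile of those columns (3.60 to 3.70), so the size of its change is uncertain. Some entries of PABPC1 (31 of 47 with different values) and PBX2 (18 of 81) repeat others.

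231T and PTX were also compared directly. TFRC was higher in 231T by 4.5, the amino acid transporters SLC7A5 and SLC7A11 by 3.61 and 3.59, PSAT1, an enzyme of serine synthesis, by 3.45, the tRNA exporter XPOT by 3.31 and UAP1, which makes a sugar nucleotide, by 3.28. CST4, a salivary cystatin, was lower by 6.12 (-6.12), and the small RNA genes RNU5D-2P (-7.02), SNORD58C (-5.91), SNORD99 (-5.65), RNU5E-2P (-5.08) and SNORD82 (-4.98) were lower as well. Limma called 10744 clusters, 5086 higher in 231T and 5658 lower, and 4106 at least 2-fold. Of the 22411 gene symbols 4788 were called (21.4%), 2909 higher and 1879 lower. Over clusters the share that was higher was 47.3% as deposited and 59.4% after centring. The count was 6842 without PTX 2, 6490 without PTX 3, 6843 without 231T 1 and 6408 without 231T 2. TRA2B was higher by 1.45 and PALM lower (-0.54), while RSRC2 (-0.51, adjusted p 0.0591), CALU (0.62, 0.255) and HNRNPM (0.21, 0.654) were not called. Of 50 named genes called, 45 kept their calls in every alternative that tested them, 19 for each gene but S100A4 (18). PALM was lost without PTX 2, PTX 3, 231T 1 or 231T 2, with a highest adjusted p of 0.0657.

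The stress response list was higher in 231T than in PTX, with 11 of 21 members up, 2 down and a median of 0.78 (camera adjusted p 0.000189, adjusted p = 0.49 with an estimated correlation). So were YAP/TEAD targets, with 9 of 18 up and 2 down, among them the muscle protein gene ANKRD1 (2.83), CCN2 (1.34) and TEAD1 (1.02) (camera adjusted p 0.0023, adjusted p = 0.49 with an estimated correlation). Replication genes were higher with 17 of 26 up and 0 down, including PRIM1 (2.42), CDC6 (2.33) and CCNE2 (1.86) (camera adjusted p 3.99e-07, adjusted p = 0.49 with an estimated correlation). SR factors had 12 of 31 up and 2 down, with SRSF10 at 1.3 (camera adjusted p 0.000158, adjusted p = 0.558 with an estimated correlation). Interferon-stimulated genes were lower with 14 of 28 down and 0 up, IFITM1 by -1.84 (camera adjusted p 3.62e-07, adjusted p = 0.49 with an estimated correlation). The p53 targets (0.0248; GADD45A 1.49) and apoptosis regulators (0.0261; BIRC2 1.99) were called up, and luminal markers (0.0261; SPDEF -1.51) and epithelial genes (0.031; KRT8 -1.24, a member of both lists) down, each with an adjusted p = 0.49 with an estimated correlation. Histones were called down (0.031; H2BC5 -1.03) and lipid synthesis up (0.0496, with 8 of 23 up and 6 down; ACAT2 1.93, MSMO1 1.92, CYP51A1 1.59), both with an adjusted p = 0.558 with an estimated correlation. Adjusted over the list alone, 12 stress response, 12 YAP/TEAD, 19 replication, 17 SR, 8 p53, 8 apoptosis and 12 lipid synthesis genes were up, and 18 interferon, 7 luminal, 8 epithelial and 6 histone genes down. In the other direction, adjusted in the same way, were 6 lipid synthesis, 3 YAP/TEAD, 3 SR, 3 p53, 2 stress response and 2 apoptosis genes (down), and 2 luminal and 2 epithelial genes (up). Members of the short counts, named after their values were seen, were DDIT4 and NUPR1 (down, stress response), ARHGEF17 and TGFB2 (down, YAP/TEAD), SRRM1 and SRRM2 (down, SR), GDF15 (down, p53), BCL2L1 and BMF (down, apoptosis), H1-1 and H2BC11 (down, histones), CLDN7, KRT19, MARVELD2 and PKP3 (down) with CLDN1 and OCLN (up, epithelial), and AGR2 and MLPH (down) with FOXA1 (up, luminal). The p53, apoptosis and lipid synthesis lists lost their calls among clusters at or above the median level, and lipid synthesis, histones and epithelial genes after quantile scaling. Of these lists, lipid synthesis lost its call without control 1, control 2, PTX 2 or 231T 1, histones without 231T 1, and epithelial genes without 231T 3. TEAD1 lost its call without control 1, 2 or 3, PTX 2 or 3, or 231T 1 or 2 (highest adjusted p over 19 alternatives 0.127). Camera called these 11 lists and 0 passed with an estimated correlation. With 1 array left out, the called rises numbered 3 to 10 for YAP/TEAD targets, 9 to 19 for replication and 10 to 19 for SR factors. They numbered 10 to 11 for the stress response, and the called falls of interferon-stimulated genes 10 to 14.

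In the lists without a camera call the named genes were PLK1, a mitotic kinase (-1.88), TUBE1 (1.17), TBCD (-0.95), ABCC3 (-1.07), NFKB1 (1.07), S100A4 (-0.74), PROCR (1.27), HNRNPH3 (1.3), DNAJB11 (1.01, with a second cluster at -0.35), HSPB1 (-1.62), PDK1 (1.1), JUN (1.15), ITGB4 (-3.04), ITGA3 (-2.08), THBS1 (2.04), CTSD (-2.86), KRT5 (-0.39), PDGFRB (-0.45), HIPK3 (1.26) and NASP (0.95). NFKB1 lost its call without PTX 2, 231T 1 or 231T 2, KRT5 without PTX 2, PTX 3, 231T 1 or 231T 2, and PDGFRB without PTX 3 or 231T 1, with highest adjusted p of 0.0569, 0.0811 and 0.0584 over 19 alternatives. The camera adjusted p of these lists lay between 0.0583 and 0.953, fry called 16 of the 29 lists, and of 12 leukocyte markers limma called 0, with 2 at an unadjusted p under 0.05. The median and the mean differed in sign for taxane transport (-0.08 and 0.08, placed down), AP-1 genes (0.05 and -0.03, placed up) and matrix genes (-0.06 and 0.07, placed up). At exon level, where the 231T columns came from another RMA run (offset SD 0.338, 99th percentile 0.961), diffSplice called 10297 of 13207 genes and the own-spread test 10799, with 9901 called by both. In simulations with 200 changed genes 66.9% and 10% of calls were false. HNRNPM (diffSplice adjusted p 3.75e-06), TRA2B (1.48e-06), TRA2A (0.00209), CALU (0.0101) and RSRC2 (0.0109) were called and PALM (0.539) was not. Here too the TRA2A call can come from the exogenous copy alone. Without PTX 3 or 231T 2 CALU had 0.069 and 0.0513, and without 231T 1 RSRC2 had 0.0615.

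The differences of PTX and of 231T from control were set side by side over all clusters, which are not independent replicates. Of the genes named and called in both comparisons, MIR3143, DUSP1, ITGB4 and GDF15 fell in both. CDC6, HNRNPM, JAG1, TUBB4B and H2AC6 rose in both. The PTX calls of these risers and of GDF15 were lost without control 3, an array that both comparisons share. SNORD117 was higher in PTX by 2.06 and lower in 231T (-1.38). Of the called clusters 71 rose in both comparisons, 408 fell in both and 33 went opposite ways. In 100 simulations of unchanged groups against the same 3 controls limma called 0 clusters the same way in both, with a mean of 0.05 calls for PTX and 0.02 for 231T. Lists as long as the observed ones, taken by smallest p from those simulations, shared 99.5 rises and 297 falls on average (85 to 113 and 265 to 325). Independent lists would share 11.03 and 44.26, a value that leaves out the shared controls, while the simulations leave out the effects. Pearson's r of the log2 fold changes was 0.256 and Spearman's rho 0.242. Unchanged groups simulated in that way gave a mean r of 0.5001, and 66.7% of clusters with the same sign in both against 57.5% observed. Both simulated values follow from sharing controls between groups of equal size and spread. Observed values below them therefore do not show that the 2 responses agree less than unchanged groups would. The covariance was 0.0431 against 0.0164 in those simulations, a difference of 0.0267. Part of the overlap may come from the shared controls, since 3 controls are too few to give each comparison controls of its own. Without PTX 1 the observed r was 0.083.

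Small RNA genes were grouped into classes after seeing the data. Of 71 H/ACA small nucleolar RNA clusters (SNORA) 3 rose and 0 fell in PTX by limma, with a median of 0.42, and 3 rose and 12 fell in 231T, with a median of -0.34. Of 189 C/D box clusters (SNORD) 11 rose and 0 fell in PTX (median 0.21), and 3 rose and 32 fell in 231T (median -0.11). SNORD117 is held by 8 clusters with equal values, so these counts hold it 8 times. Members of the short counts, named after their values were seen, were SNORA20, SNORA37 and SNORA65 (up in PTX), and SNORA10, SNORA55, SNORA5C, SNORD16, SNORD51 and SNORD75 (up in 231T). Of 215 U RNA clusters (RNU), small nuclear RNAs and their pseudogenes, 2 rose and 50 fell in 231T, with a median of -0.28; the risers, named after their values were seen, were RNU12 and RNU7-59P. Of 58 Y RNA clusters 10 fell in 231T (median -0.33). Of 21 Cajal body RNAs (SCARNA) SCARNA22 rose and SCARNA7 and SCARNA10 fell in 231T, again named after their values were seen, with a median of -0.03 that became 0.03, 0.03 and 0.04 after quantile scaling, cyclic loess and centring. In PTX the SCARNA median was 0.42, with SCARNA7 called up, also named after its values were seen. In PTX the U RNA and Y RNA medians were 0.17 and 0.03, and limma called 0 clusters of either class, with 45 higher and 10 lower U RNA and 6 higher and 3 lower Y RNA clusters at an unadjusted p under 0.05. Of 1106 microRNA clusters 41 rose and 70 fell in 231T, with a median of -0.02 that became 0.03, 0.01 and 0.05 under those scalings, and 3 fell in PTX (median 0): MIR3143, and MIR378D2 and MIR549A, named after their values were seen. The SNORA, SNORD, U RNA and Y RNA medians kept their sign under those scalings. The arrays of a group differed: relative to the mean of 9 arrays the SNORA median was -0.06 in PTX 1, 0.78 in PTX 2 and 0.55 in PTX 3, and -0.39, 0.06 and 0.07 in control 1, 2 and 3. In 231T 1, 2 and 3 it was 0.01, -0.59 and -0.41, so 231T 1 lay above control 1 and below control 2 and control 3. The SNORD median of 231T 3 (-0.07) lay above those of control 1 (-0.08) and control 3 (-0.10), and 57.7% of SNORD clusters were lower in 231T, against 58.4% of protein-coding clusters.

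**Figure D4:**
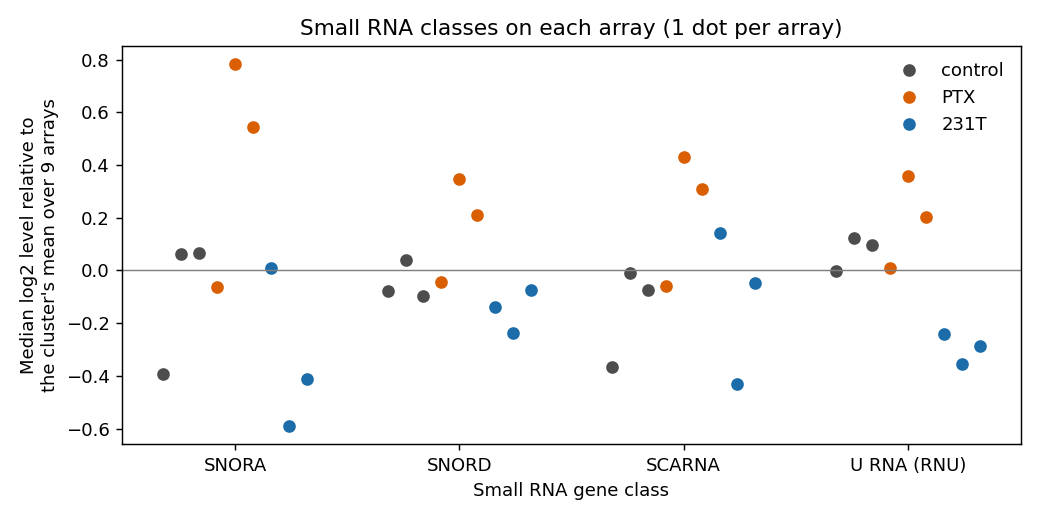
Median log2 level of SNORA, SNORD, SCARNA and U RNA clusters on each array (dots), relative to the mean of each cluster over 9 arrays (vertical axis). U RNA medians in 231T lay between -0.36 and -0.24, and the SNORA median of PTX 1 (-0.06) lay below those of PTX 2 (0.78) and PTX 3 (0.55).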

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

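All tests here, and the criteria they were judged by, were chosen after the result was seen. A first version of the criteria for the spike-in sets, the exon-region sets and the small RNA yield read each result as favouring the technical explanation, and the criteria were tightened to need both classes of probe set after that outcome was known. The bound for the offset between runs was raised from a value over all levels, which 9943 genes passed, to the highest of any level after that count was known.

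Signals appeared in probe sets outside the comparisons. Of 92 ERCC spike-in sets, limma called 27.17% in 231T against control (95% exact interval 18.4 to 37.5), and of 63 sets of the ERCC mix step 42.86% (30.5 to 56.0, against 27.1% of clusters of the same level). Of 23 antigenomic background sets 3 were called (13.0%, against 12.4% of clusters of the same level), and the median difference of the 23 was 0.07. Those 3, with 11, 12 and 13 G or C bases, were higher in 231T than in control by 0.93, 0.84 and 0.76 (limma adjusted p 0.00473, 0.0056 and 0.00707). The highest median absolute difference between the gene-level and exon-level tables for a control or PTX array was 0.253.

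The breadth of the 231T difference at gene level was 10814 calls. Hybridisation or labelling that differed between arrays was tested on the spike-in sets: ERCC sets were called in 27.17% against 18.3% of clusters of the same level, but limma called 0 of 8 bacterial spike-in sets (upper limit 36.9%, 1 at an unadjusted p under 0.05) against 48.8%. Of the called ERCC sets 23 were higher and 2 lower in 231T, and of the called mix-step sets 26 were higher and 1 lower. Against PTX, 25 ERCC and 29 mix-step sets were called higher in 231T and 0 lower. Over all clusters, 4837 calls against control were higher and 5977 lower. The ERCC and bacterial classes disagree, and the bacterial class holds only 8 sets. This explanation and the effect of TRA2A thus cannot be told apart here. Whether ERCC RNA was added is not stated in the sources used here, and unspiked ERCC sets could read other RNA. The effect of TRA2A itself and that of introducing it stay open and were not tested. Whether the gene-level 231T columns came from a run of their own was not tested either.

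Exon use differed between 231T and control in 10378 genes by diffSplice and 10874 by own spread. Of the diffSplice genes 6115 held a called relative change above the highest 99th percentile of the offset in any of 10 groups of level (1.7). By the meaning of a 99th percentile, 1% of the 186741 tested probe sets, or 1867 sets, could pass it from the other processing run alone. That is a count of probe sets, which could give at most as many genes, while 6115 counts genes. A smaller real change that adds to an offset can pass 1.7 too, and such cases were not counted. The comparison of 6115 with 1867 argues against the run as the whole cause only if other sets of a level were offset like the 1465 shared ones. The median and 75th percentile of exon-region sets with 1 symbol were 5.22 and 7.58. Of the 10 groups only the lowest, of 146 sets, lay at or below 7.12, too few to bound dim sets. For dim sets, and for genes below the bound, the run stays open. The gene-level table was taken to come from 1 run, which was not tested. There 39.52% of 1465 exon-region and junction sets were called in 231T against control, with 42.9% of clusters of the same level and 3.75% in PTX against control. That leaves hybridisation or labelling open, as the spike-in classes disagree, and TRA2A as a splicing regulator may account for part and was not tested.

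SNORA and U RNA clusters were lower in 231T than in control in 70.4% and 80.5% of cases, against 58.4% of protein-coding clusters, while the SNORD share was 57.7% and the SNORA median of 231T 1 (0.008) lay above that of control 1. Less RNA of the host genes was tested on 84 pairs of a snoRNA and the 1 longer gene whose span holds it. The strand was not checked, so some of these 69 genes may not be hosts, and pairs that share a gene were treated as independent. Spearman's rho was 0.055 (95% bootstrap interval -0.176 to 0.272, permutation p = 0.62), and 71.4% of the snoRNAs but 29.8% of the genes paired with them were lower. That argues against it for these pairs, as far as the genes are true hosts. A lower yield of small structured RNA stays open: 72.15% of SCARNA and Y RNA clusters were lower, but the SCARNA share was 52.4% (29.8 to 74.3) and the Y RNA share 79.3% (66.7 to 88.8). An effect of TRA2A on these RNAs could not be separated from it and was not tested.

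Each comparison of 3 against 3 samples has 10 splits, too few for a share under 0.05. At gene level 1 of the 10 splits, the real one, gave as many calls in each comparison, with 654, 10814 and 10744 calls and a highest other split of 0 by limma. For exon use the real splits gave 798, 10378 and 10297 genes by diffSplice and the highest others 152, 51 and 184. By own spread they gave 13, 10874 and 10799, and the highest others 1, 0 and 1.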

How the results depend on the processing

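The test of each probe set's own spread, counting identical entries once and the bounds from the offset between runs were chosen after seeing the data, and the other alternatives before. Calls for PTX against control numbered 302 at 2-fold or more, 128 with the replicate number as a block, 1181 among clusters at or above the median, 308 with trend and robust settings, 99 with only the 2 groups and 1284 with array weights. For 231T against control and against PTX they were 4248 and 4106 at 2-fold or more, and 7181 and 6581 among clusters with 1 symbol, where fewer were tested. The TRA2A difference in PTX passed the threshold at 1.1 after quantile scaling (adjusted p 0.0428), 1.15 after cyclic loess (0.0373), 1.04 among clusters at or above the median (0.0423) and 1.04 among clusters with 1 symbol (0.0325), over a range of 0.0325 to 0.177. Lists past camera were 0, 0 and 0 with an estimated correlation, and fry gave 3 for PTX and 12 for 231T against control. Exon use in PTX gave 1544 genes without a filter, 322 at the 75th percentile, 1659 with junctions and 13 by own spread, and 6168 and 6124 at the 75th percentile and 6115 and 6626 above the offset at any level for 231T against control and PTX. Leaving out 1 array gave 100 to 1025, 7122 to 11687 and 6408 to 12283 calls for the 3 comparisons, TRA2A differences of 0.84 to 1.2, 2.28 to 2.6 and 1.26 to 1.62, a shared r of 0.083 to 0.343, 9 to 11, 6 to 8 and 9 to 13 lists, and exon use by diffSplice in 328 to 1138, 8845 to 10713 and 9007 to 10298 genes. Values that changed sign, of genes that were not called, were CALU in 231T (0.07 after quantile scaling), RSRC2 in PTX (-0.02 with array weights, -0.01 without control 2, and -0.15 without PTX 1 to 0.14 without PTX 2) and TRA2B in PTX (-0.01 without PTX 1 to 0.53 without PTX 3). Apart from fewer clusters tested, the cause was not tested. Among single genes at gene level 2433 values kept direction and side of the threshold, 263 lost and 15 gained a call, and at exon level 305, 14 and 5. Other background corrections of the scanner files were not run. Levels close to the background sets limit dim genes.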
